A study of Drosophila melanogaster with 4 samples.

How the data were processed

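Messenger RNA was sequenced from adult male Drosophila melanogaster of 4 genotypes, per the labels: the V966M and 51B alleles of Ago2, each as a homozygote and as a heterozygote over a TM3 balancer chromosome. A balancer is a rearranged chromosome that suppresses recombination and carries visible markers. The flies were 0 to 16 hr old and were grown at 25 °C. Total RNA was isolated with Trizol, and standard Illumina libraries were made, per the labels' protocols.

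The deposited table held 13990 genes with 1 FPKM value (fragments scaled by transcript length and by the number of mapped fragments), the lower and upper bound of an interval around it, and a quantification status for each genotype, per the file headers. TopHat and Cufflinks were used with genome build dm3, per the submitters' processing notes; versions, the annotation and the strand setting are not given in the sources used here. The design text states that every genotype was sequenced 2 times, whereas the table holds 1 value per genotype, so each genotype entered as n = 1. The interval level is not stated in the table, and it is called the deposited interval. It was symmetric around the FPKM value, within a relative tolerance of 0.0001, in all 51072 values whose lower bound was above 0. FPKM values carry no read counts, so depth is unknown, and no counting interval or detection limit was computed. The width of the deposited interval was used in its place as the measure of precision. Loci are those of the table, in dm3, with the start converted to count from 1. The table gives one locus to all overlapping genes of a cluster, and 5176 genes shared theirs. The reference annotation used here is of a later build and served only to match gene lengths by symbol. Of 6669 genes with a locus of their own, 1180 had the reference length if the deposited start counted from 0 and 109 if it counted from 1.

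Genes with status OK in all 4 genotypes (13197) and a mean FPKM of at least 1 were analysed, which left 10872 genes. The change of a gene was log2((FPKM + 1)/(FPKM + 1)), a scale that understates the change of genes with low values. A gene was called higher or lower where the change was at least 2-fold on this scale and the deposited intervals of both genotypes did not overlap. With 1 value per genotype there was no replicate check, no test between genotypes and no p-value. The homozygote was compared with the heterozygote within each allele, the heterozygotes of both stocks with each other, and the homozygotes of both stocks with each other. Values were used as deposited. In an alternative set before the data were examined, each genotype was divided by its median ratio to the geometric mean over genotypes, with factors of 1.13 for the V966M heterozygote, 0.936 for the V966M homozygote, 0.932 for the 51B heterozygote and 1.02 for the 51B homozygote. Results under this alternative are called rescaled. It moved the median change of all genes by more than 0.1 in each comparison: from -0.25 to -0.00 in V966M, from 0.07 to -0.04 in 51B, from 0.26 to 0.02 between heterozygotes and from -0.11 to -0.01 between homozygotes.

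The gene lists were fixed before the data were examined: 25 lists of small RNA pathways, transposable elements, immune, stress and detoxification genes, markers of tissues a male holds, female-specific and ovary genes, dosage compensation, circadian clock and chromatin regulators, balancer markers, histones and housekeeping complexes. For each list with at least 3 analysed members, the median log2 change was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins and drawn with replacement within a bin. Its percentile is the percent of random lists with a lower median, and a list counted as standing apart outside the central 95%. Random lists were drawn gene by gene and matched on expression alone. They do not carry the shared changes of list members from the same tissue or of near-identical copies. For such lists the central 95% can be too narrow, so a percentile is not a p-value and does not stand for independent genes. The list of transposable elements had 0 members in the table. Fixed with them was the rule for named genes: AGO2, the 10 called genes with the largest change in each direction per allele, genes called in both alleles, up to 5 called in opposite directions, up to 4 members of each list with the largest change in either allele, and all measured members of the siRNA, hairpin RNA and balancer lists. Genes named outside the rule were chosen after their values were seen: Arc2, CG7739, AttA, CecA1, IM4, IM10, PGRP-SA, PGRP-SC1a, PGRP-SC1b, PGRP-SC2, PGRP-SD, TotA, TotM, LysB, LysD, LysX, LysP, the Jonah genes other than Jon74E, Jon25Bi, Jon44E and Jon99Ci, Cht4, CG13422, Rfabg and the members of the lists in the next sentence. Added after the data had been seen were a list of gut epithelium genes other than digestive enzymes, a list of fasting and insulin signalling genes, all other genes whose symbols start with Cpr (cuticle proteins) and all genes whose symbols start with Sfp (seminal fluid proteins). The look at the chromosome 4 genes and at the heterochromatin scaffolds followed from medians per chromosome arm.

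Alternatives set before the data were examined were thresholds of 1.5-fold and 4-fold, pseudocounts of 0.1 and 5 FPKM, no filter on low values, a mean FPKM of at least 5, calls without the intervals, rescaling, genes of chromosome 3 left out, and every gene regardless of status. Leaving out genes that shared a locus and leaving out genes listed at 0 were added after seeing the data. Shares of called genes have exact binomial intervals, and medians per arm have percentile intervals from 2000 bootstrap draws over genes. These intervals describe the spread between genes within these libraries. The calling rule was tested on simulated values of the 10872 genes, with the deposited half-width taken as 1.96 SD. At each fold, 50 genes with at least 5 FPKM in the heterozygote were changed. For the V966M comparison the rule recovered 2% of genes changed 1.5-fold, 86% at 2.5-fold, 98% at 4-fold and 100% at 8-fold, and called 2 of 10672 unchanged genes. For the 51B comparison it recovered 0%, 68%, 100% and 100% at those folds and called 11 of 10672. The simulated noise came from the deposited intervals alone, without variation between flies or libraries and without a shift of all genes. The calls of unchanged genes are therefore no false-positive rate for these data. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.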

Results

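Gene expression was measured by mRNA sequencing in adult males carrying 1 of 2 alleles of Ago2, which encodes the Argonaute protein that loads small interfering RNAs (siRNAs). The 4 genotypes were the V966M heterozygote, the V966M homozygote, the 51B heterozygote and the 51B homozygote, with 1 value per gene and genotype and no replicates. Summed FPKM came to 645245, 523951, 493829 and 573226 in that order. The deposited interval was narrower in the middle pair: among genes with at least 5 FPKM, its median half-width was 24.9% of the value in the V966M heterozygote, 16.6% in the V966M homozygote, 15.7% in the 51B heterozygote and 29.2% in the 51B homozygote. Listed at 0 were 502, 447, 421 and 415 genes, respectively.

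AGO2 itself was lower in the homozygote of 51B and was not called in V966M. In the 51B stock its level was 46.5 FPKM (deposited interval 39.7 to 53.3) in the heterozygote and 6.33 FPKM (4.50 to 8.16) in the homozygote, 7.35-fold lower, with a log2 change of -2.70. The V966M stock had 150.0 FPKM (111 to 189) in the heterozygote and 101 FPKM (83.4 to 118) in the homozygote, a log2 change of -0.57 with overlapping intervals. Rescaling gave -2.82 and -0.30. The gene lies on 3L, in a locus from 15547217 to 15556163 in dm3 that it shares with CG7739. That neighbour had 17.1 FPKM in the 51B heterozygote and 21.8 FPKM in the 51B homozygote.

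The question put to the small RNA lists was whether components and targets of these pathways differed with Ago2. AGO2 in 51B was the single call among the 6 analysed siRNA pathway genes. Dcr-2, which makes siRNAs, had 10.6, 7.22, 6.78 and 5.88 FPKM in the order V966M heterozygote, V966M homozygote, 51B heterozygote, 51B homozygote. Its partner r2d2 had 8.45, 6.79, 5.36 and 5.23 FPKM, and loqs had 34.1, 32.7, 43.0 and 48.7 FPKM. The genes trsn and Trax were not called either, and Hen1 was left out because its quantification had failed in the V966M homozygote. No call was made among 5 miRNA pathway genes (median log2 change -0.31 in V966M and 0.14 in 51B), 10 piRNA pathway genes (-0.24 and -0.02) or 8 hairpin RNA precursors and their known targets (-0.27 and -0.18). The largest change in the last list was that of mus308, a DNA repair polymerase gene and known target of siRNAs from the CG4068 hairpin. It had 5.13 FPKM (4.31 to 5.94) in the 51B heterozygote and 9.75 FPKM (7.10 to 12.4) in the 51B homozygote. These intervals did not overlap, the log2 change of 0.81 stayed below the threshold, and the gene shares its locus with another. In V966M, mus308 had 3.35 and 2.74 FPKM. The CG4068 hairpin RNA had 123 FPKM in the 51B heterozygote and 166 FPKM in the homozygote. CR18854 was left out because its quantification had failed in the V966M heterozygote. No other member, among them CG8289, CR32207, CR32205, pncr009:3L and ATPsyn-beta, was called in either allele.

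**Figure D1:**
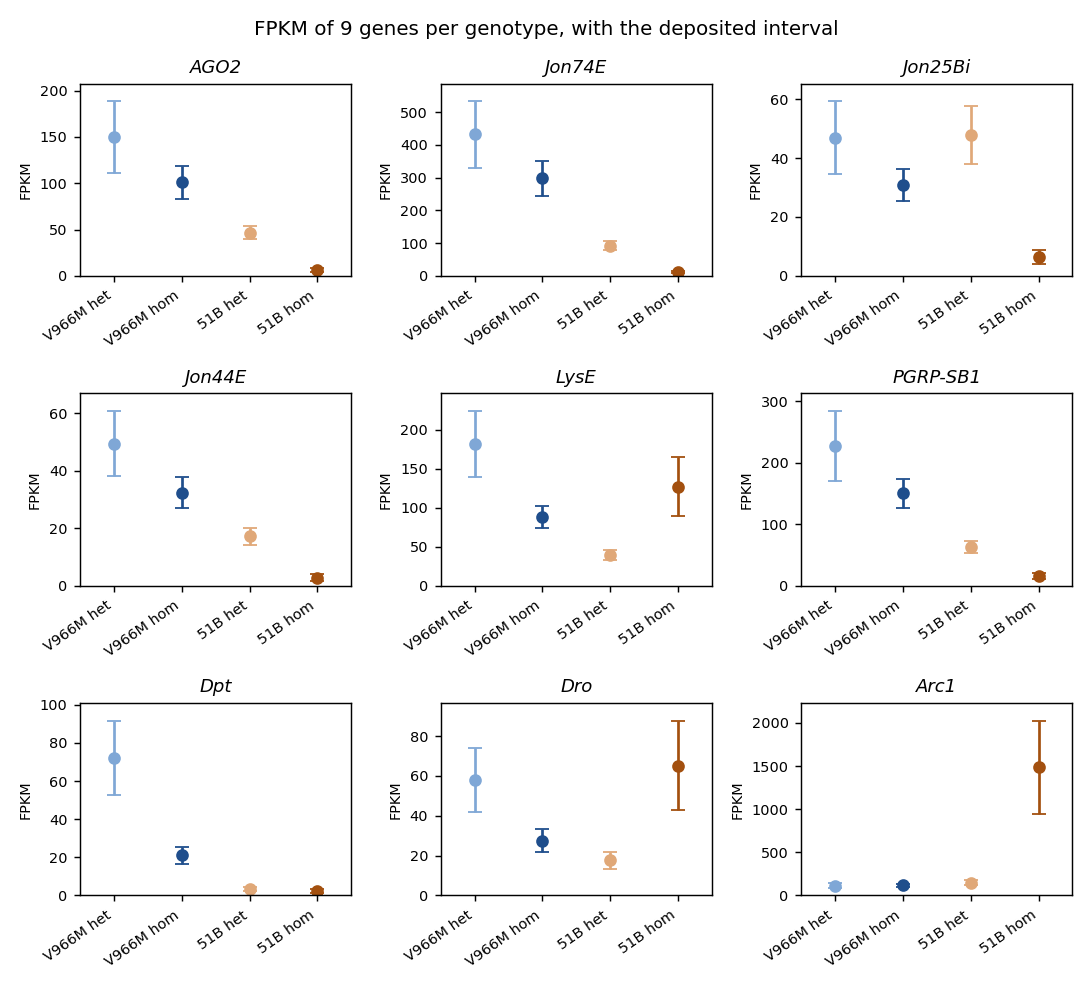
FPKM (vertical axes, linear, from 0) of 9 genes in the 4 genotypes (horizontal axes, het for heterozygote and hom for homozygote); points are the deposited values, 1 per genotype, and bars the deposited intervals. AGO2, Jon74E and PGRP-SB1 were lowest in the 51B homozygote, at 6.33, 10.8 and 15.2 FPKM, whereas Arc1 was highest there, at 1486 FPKM.

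Few genes separated the V966M homozygote from its heterozygote, and those that did included antimicrobial peptide genes and ple, the tyrosine hydroxylase gene of dopamine and cuticle pigment synthesis. Dpt, an antimicrobial peptide gene, had 72.2 FPKM (52.8 to 91.6) in the heterozygote and 21.0 FPKM (16.5 to 25.5) in the homozygote, and its neighbour DptB had 104 FPKM (76.4 to 131) and 39.1 FPKM (31.4 to 46.8). The level of ple was 266 FPKM (189 to 344) and 108 FPKM (88.5 to 127). AttB went the other way, with 17.6 FPKM (13.2 to 22.0) and 36.7 FPKM (30.6 to 42.9). In all, 7 genes were higher and 38 lower in the homozygote, 16% higher. After rescaling, 13 were higher and 8 lower, 62% higher, and 15 of the 21 had also been called as deposited. The median log2 change of all genes was -0.25 as deposited, so the excess of lower calls moved with the scale.

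The most changed genes in V966M included several at or near 0 in one genotype. CG42529, on 3L, was listed at 0 in the V966M heterozygote and had 28.5 FPKM (24.6 to 32.5) in the homozygote, and 46.4 and 78.7 FPKM in the 51B heterozygote and homozygote. CG32857, on X, had 0.0180 and 13.7 FPKM in V966M and 14.7 and 36.5 FPKM in 51B. Both share their loci with other genes, as does CG33498, so their values depend on how fragments were divided. The remaining higher genes were dro3, CG1850 and CG15597, with 5.77, 4.84 and 22.7 FPKM in the homozygote against 1.74, 1.77 and 10.6 FPKM. Among lower genes, CG31683 had 7.16 FPKM in the heterozygote and 0.908 FPKM in the homozygote, CG32335 had 7.81 and 2.45 FPKM, SP555 had 3.15 and 0.687 FPKM, and CG17325 had 4.29 and 1.15 FPKM. The small nuclear RNA gene snRNA:U1:21D was lower as deposited (log2 change -1.88), and after rescaling its change was -1.75 but its intervals overlapped. For snoRNA:U3:54Aa the change was -1.23 as deposited and -0.99 after rescaling, short of the threshold.

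By list, 6 of the 24 measured lists stood apart from random lists in V966M. Members of a list can change together, so percentiles in either allele place a list within these libraries only. Male accessory gland protein genes, which encode seminal fluid proteins, had a median log2 change of -0.48 (percentile 0.01), with Mst57Dc lower among 19 members and not called after rescaling. Digestive enzyme genes of the gut had a median of -0.41 (0.07), with LysE lower among 28 and not called after rescaling. For 87 cytosolic ribosomal protein genes the median was -0.37 (0.01), with 0 calls. Larval serum and fat body genes (median -0.01, percentile 99.99), cuticle and eclosion genes (-0.01, 99.97) and oxidative phosphorylation genes (-0.17, 99.22) lay above random lists, with 0 calls. With chromosome 3 genes left out, the cuticle list (3 genes left, median -0.29, percentile 39.2) and the oxidative phosphorylation list (97.48) no longer stood apart. Relative to the shift of all genes, the rescaled medians of the full larval serum, cuticle and oxidative phosphorylation lists were 0.26, 0.16 and 0.10. Those of the accessory gland, digestive and ribosomal lists were -0.22, -0.13 and -0.10. Of 28 antimicrobial and stress-induced humoral genes, AttB was higher and Dpt, DptB, AttC and Dro lower (percentile 63.9). After rescaling AttA joined AttB, and AttC and Dro were no longer called.

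The 51B homozygote differed from its heterozygote in genes that included the protease gene Jon74E and the peptidoglycan recognition gene PGRP-SB1, which were lower, and Arc1, which was higher. Arc1, a neuronal gene with a retroviral Gag-like capsid domain, lies on 2R from 10245430 to 10247799. It had 147 FPKM (116 to 177) in the heterozygote and 1486 FPKM (947 to 2025) in the homozygote, 10.1-fold higher, and 112 and 116 FPKM in V966M. Jon74E, a Jonah serine protease gene, had 92.2 FPKM (78.3 to 106) and 10.8 FPKM (7.29 to 14.3), 8.53-fold lower, and PGRP-SB1 had 63.0 FPKM (53.3 to 72.7) and 15.2 FPKM (10.1 to 20.2). In all, 184 genes were higher and 122 lower, 60% higher. After rescaling, 140 were higher and 158 lower, 47% higher, and 262 of these had also been called as deposited.

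Beside Arc1, the genes with the largest changes to higher values were Cyp4e3, a cytochrome P450 gene, with 35.8 and 261 FPKM, CG8620 with 14.6 and 108 FPKM, CG6908 with 18.2 and 129 FPKM, Cpr64Ac, a cuticle protein gene, with 6.27 and 42.8 FPKM, and Uro, the urate oxidase gene, with 24.8 and 149.5 FPKM. CG14245, CG42365 and CG11796 were also among the first 10. CG10102 had 135 and 1475 FPKM, but its deposited locus is that of Arc2 while its level was close to that of Arc1, so its identity is uncertain. Arc2 had 6.69 and 39.4 FPKM. Beside Jon74E and AGO2, the largest changes to lower values were those of Jon25Bi with 47.9 and 6.37 FPKM, BG642312 with 48.6 and 8.86 FPKM, CG42825 with 7.38 and 0.693 FPKM, Jon44E with 17.1 and 2.82 FPKM, and CG7882, CG8562, CG5932 and CG34329. All 20 kept their calls after rescaling.

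Digestive enzyme genes differed in both directions in 51B. Of 28 members, 10 were lower: Jon25Bi, Jon25Bii, Jon44E, Jon65Ai, Jon74E, Jon99Ci, Jon99Cii, Jon99Ciii, Jon99Fi and LysP. LysP is a lysozyme gene, as are the 4 higher members LysB, LysD, LysE and LysX. LysE had 39.0 FPKM (32.5 to 45.6) in the heterozygote and 127 FPKM (88.8 to 165) in the homozygote. The remaining 14 members were not called, among them Jon65Aii (log2 change 0.33), Jon99Fii (0.09) and the trypsin genes. The list's median log2 change was -0.34, and 0 of 10000 random lists had a median as low. Rescaling left these calls and added Jon25Biii as lower. Near-identical copies such as LysB, LysD and LysE or Jon99Cii and Jon99Ciii can exchange fragments, so single members of these clusters are uncertain.

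Of 28 humoral immune and stress-induced genes in 51B, 6 were lower (AttC, CecA1, PGRP-SB1, PGRP-SC2, TotC and TotX), 2 were higher (Dro and IM10) and 20 were not called, with a median of -0.61 and 0 of 10000 random lists as low. TotC, a stress-induced gene, had 62.9 and 16.1 FPKM. IM4 was lower as well after rescaling. Accessory gland genes had a median of -0.50, with 0 of 10000 random lists as low and Acp24A4 (54.3 and 19.2 FPKM) and PebII (259 and 123 FPKM) lower among 19. Testis genes (median -0.09, percentile 0.67), muscle genes (-0.06, 1.98) and oxidative phosphorylation genes (-0.05, 2.16) also lay below random lists, with 0 calls as deposited and TpnC41C lower after rescaling. With chromosome 3 genes left out, the testis list (percentile 42.5) and the oxidative phosphorylation list (5.94) no longer stood apart, nor did the latter without genes sharing a locus (20.5).

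Lists above random lists in 51B were detoxification, larval serum and fat body, cuticle, neuronal, photoreceptor and heat shock genes. Among 20 detoxification genes (median 0.53, 0 of 10000 random lists as high), 4 were higher, 2 lower and 14 not called, and after rescaling 3 were higher. GstD5 had 2.12 and 11.3 FPKM, GstD2 had 6.80 and 28.1 FPKM, and Cyp6a8 had 2.88 and 11.3 FPKM. GstD3 was among the lower members. Larval serum and fat body genes had a median of 0.54 (percentile 99.97) and went both ways: Lsp1beta (41.2 and 126 FPKM) and Lsp2 (112 and 298 FPKM) were higher, and Lsp1gamma (2.34 and 0.543 FPKM) and fit (1.95 and 0.449 FPKM) lower. After rescaling Rfabg was lower too. The 11 cuticle genes (0.39, 99.39) and 9 neuronal genes (0.46, 99.3) had 0 calls. With chromosome 3 genes left out, the neuronal (median -0.0191, percentile 29.7), cuticle (85.3, with 3 genes left) and photoreceptor (79.0) lists no longer stood apart. Of 16 photoreceptor genes (0.39, 99.1), the opsin gene Rh6 was higher (39.1 and 108 FPKM) and Rh5 lower (10.03 and 3.75 FPKM). Hsp22 was higher among 15 heat shock genes (140 and 443 FPKM; list median 0.31, percentile 98.19), and Hsp70Aa and Hsp70Ab were higher as deposited and not after rescaling. All 15 lie on chromosome 3, and the list no longer stood apart with a mean of at least 5 FPKM (percentile 91.6), a pseudocount of 5 FPKM (96.8) or without genes sharing a locus (96.1).

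The other lists lay within the central 95% of random lists in 51B as deposited. Odorant-binding genes had a median of 0.13 (percentile 52.5), with Obp99d, Obp99b and Obp99c higher among 12, and Obp99b at 230.5 and 719 FPKM. These 3 genes lie on 3R, and without chromosome 3 genes the list stood below random lists (median -0.47, percentile 0.03). Of 5 female-specific and ovary genes, the chorion gene Cp15 was higher (4.68 and 10.9 FPKM) and not called after rescaling. No calls were made among 7 dosage compensation genes (median -0.37 in V966M and 0.07 in 51B), 7 circadian clock genes (-0.17 and -0.02), 16 Polycomb, trithorax, Hox and insulator genes (-0.19 and 0.10), 4 histone genes (-0.30 and 0.53) or, in 51B, 87 ribosomal protein genes (0.24). Balancer markers were checked because only heterozygotes carry TM3. In 51B, y, which shares its locus with another gene, was lower in the homozygote (3.53 and 1.01 FPKM), whose heterozygote carries a y+ marker per its label, and e was higher (73.0 and 156 FPKM; not called after rescaling). In V966M neither y (12.2 and 8.30 FPKM) nor e (81.3 and 53.5 FPKM) was called, and e went the other way. Sb, Ser and twi were not called in either allele.

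Genes that differed in both alleles were few. CG15597 and CG32857 were higher in both homozygotes, where independent lists of these sizes would share 0.118 genes, and the immune gene AttC and CG42825 were lower in both, against 0.426. CG32857 and AttC share their loci with other genes. Opposite directions were called for CG33498, higher in V966M and lower in 51B (0.0786 by independent lists), and for Dro, LysE and CG8483, lower in V966M and higher in 51B (0.643). After rescaling, CG32857 and Cht4 were higher in both and none was lower in both, and CG33498 and CG13422 were higher in V966M and lower in 51B. Across the 10872 genes, which are not independent replicates, the changes in both alleles had Pearson's r of 0.264 (bootstrap interval 0.239 to 0.289) and Spearman's rho of 0.279. Of the 184 genes higher in 51B, 131 were above 0 in V966M after rescaling, and of the 122 lower, 100 were below 0, where 48.9% of all genes were above 0.

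**Figure D2:**
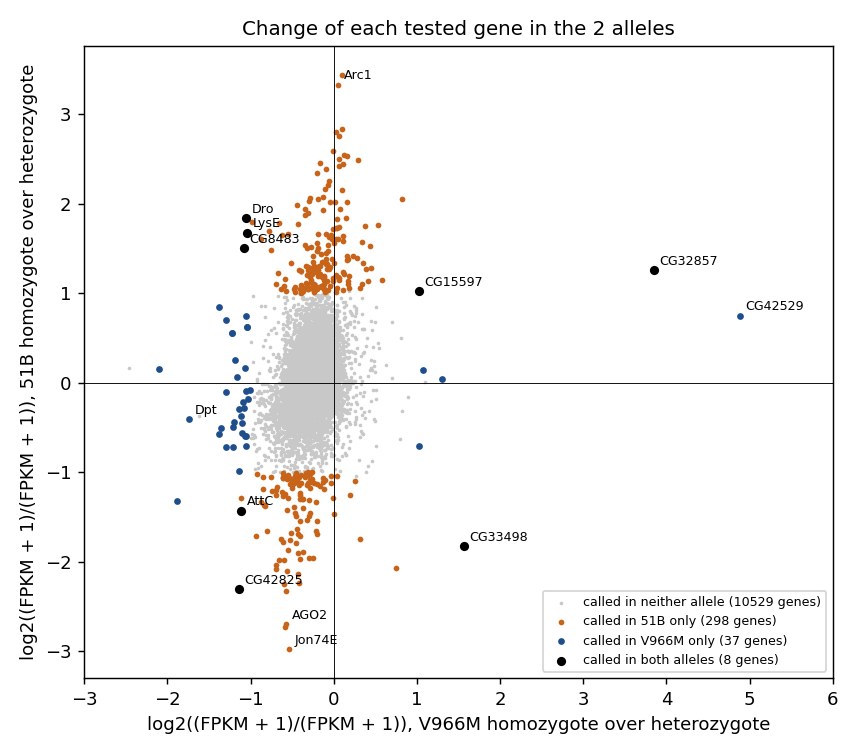
log2 change of each of 10872 genes as deposited, V966M homozygote over heterozygote on the horizontal axis and 51B homozygote over heterozygote on the vertical axis; each point is a gene, coloured by the alleles in which it was called. The 298 genes called in 51B alone spread along the vertical axis, the 37 called in V966M alone along the horizontal axis, and 8 were called in both.

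Immune and digestive genes were among those that differed between the stocks at matched zygosity. The V966M heterozygote had more than the 51B heterozygote of 17 of 28 humoral genes and less of 4 (TotA, TotC, TotM and TotX), and more of 21 of 28 digestive genes and less of 0. Dpt was at 72.2 FPKM in the former and 3.33 FPKM in the latter, and Jon74E at 432 and 92.2 FPKM. After rescaling these counts were 16 and 4, and 14 and 0. Between homozygotes, 18 humoral genes were higher in V966M and 2 lower (Dro and TotA), and 16 digestive genes were higher and 1 lower (LysD). Rescaling gave 18 and 2, and 18 and 1. The siRNA target mus308 was lower in the V966M homozygote than in the 51B homozygote (2.74 and 9.75 FPKM), also after rescaling. CG4068 (78.3 and 166 FPKM) was lower as deposited and not after rescaling. Other lists stood apart between stocks as well. Between heterozygotes, testis genes (median -0.36, percentile 0) and the hairpin RNA list (-0.21, 0.32) lay low in V966M and photoreceptor genes high (0.53, 99.2), with 0 calls, and of 11 cuticle genes (0.54, 98.8) 3 were higher, 1 after rescaling. Of 10 fasting and insulin signalling genes, a list added after the data were seen (0.56, 98.6), 2 were higher, 1 after rescaling. Between homozygotes, V966M was low in testis genes (-0.69, 0.01; 4 lower, 1 after rescaling), heat shock genes (-0.73, 0; 3 lower, also after rescaling), detoxification genes (-0.72, 0; 2 higher and 6 lower, 3 and 3 after rescaling) and ribosomal protein genes (-0.28, 1.56; 0 calls). It was high in accessory gland genes (0.48, 100; 1 higher, 3 after rescaling), muscle genes (0.32, 99.7; 1 higher), circadian clock genes (0.27, 98.6) and oxidative phosphorylation genes (0.27, 99.2), the last pair with 0 calls. Over all genes, 297 were higher and 33 lower in the V966M heterozygote (90% higher), and 134 and 78 after rescaling (63% higher), with 167 genes called both ways. Between homozygotes, 299 were higher and 302 lower (50% higher), and 362 and 198 after rescaling (65% higher), with 497 called both ways.

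Calls per chromosome arm were counted because Ago2 and the balancer lie on chromosome 3. Of the 306 genes called in 51B, 164 lay on 3L and 3R, 53.6% (exact interval 47.8 to 59.3), where 43.8% of analysed genes lie. After rescaling, 151 of 298 lay there. For V966M these counts were 21 of 45 as deposited and 7 of 21 after rescaling. The share of analysed genes called in 51B was 3.17% on 3L, 3.66% on 3R, 3.21% on 2R, 2.25% on 2L and 1.42% on X. In V966M it was 0.528%, 0.373%, 0.504%, 0.245% and 0.114%. Of the 74 genes of chromosome 4, 4 were called in V966M, all lower, and 0 in 51B. After rescaling these counts were 0 and 1. After rescaling, the median log2 change on chromosome 4 was -0.38 (bootstrap interval -0.46 to -0.32) in V966M and -0.41 (-0.45 to -0.38) in 51B, and for 47 genes of the heterochromatin scaffolds it was -0.25 (-0.32 to -0.16) and -0.40 (-0.58 to -0.36). On the other arms the medians lay between -0.07 and 0.05 in both alleles.

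**Figure D3:**
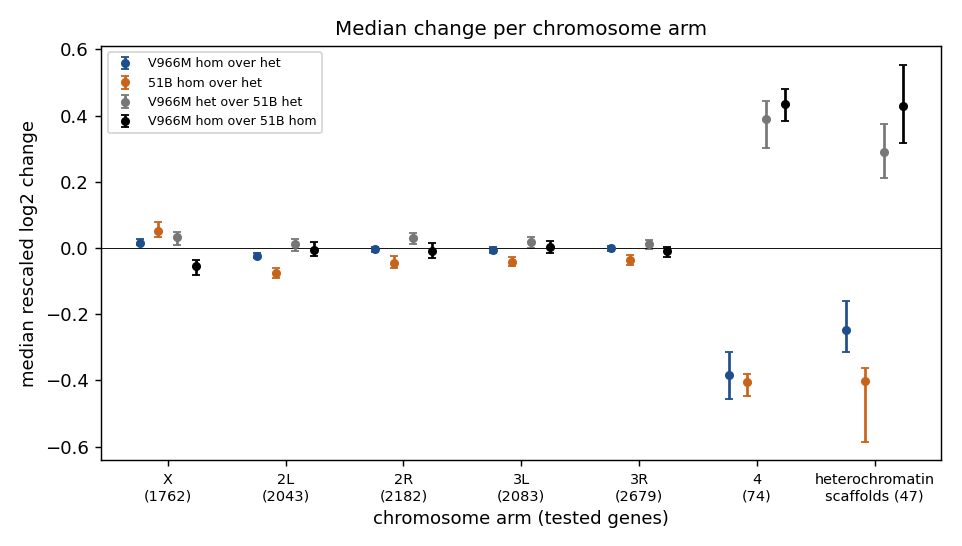
Median rescaled log2 change per chromosome arm and for the heterochromatin scaffolds (horizontal axis, analysed genes in brackets) in the 4 comparisons; bars are bootstrap intervals over genes. Genes of chromosome 4 lay at -0.38 and -0.41 in the V966M and 51B homozygotes over their heterozygotes, and at 0.39 and 0.44 in V966M over 51B.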

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

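Each result here was singled out because the alleles moved in opposite directions past the threshold, with 1 value per genotype. The difference between alleles was not tested in any of them. CG33498 was higher in the V966M homozygote (0.000561 and 1.95 FPKM) and lower in the 51B homozygote (2.56 and 0.00104 FPKM), a difference of log2 changes of 3.39. It shares its locus with another gene, and its 2 lower values lie near 0, so no fold is given. Dro, an antimicrobial peptide gene, had 58.1 and 27.5 FPKM in V966M and 17.5 and 65.2 FPKM in 51B (difference -2.89). LysE had 182 and 87.8 FPKM and 39.0 and 127 FPKM (-2.72), and its near-identical neighbours LysB and LysD had 527 and 288, and 547 and 276 FPKM in V966M, and 149.6 and 459, and 173 and 602 FPKM in 51B. CG8483 had 67.9 and 31.6 FPKM and 37.6 and 109 FPKM (-2.59). After rescaling, the lower calls of Dro, LysE and CG8483 in V966M were lost and their higher calls in 51B held.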

How the results depend on the processing

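No paired analysis was possible because, within each comparison, every genotype has 1 value and no replicate number, so no replicate could be left out either. A joint fit over both stocks with allele as a block, which would treat the alleles as replicates and leave 1 residual degree of freedom, was not run. The alternatives that left out genes sharing a locus or listed at 0 were chosen after seeing the data. Unless a construction is named, the cause was not tested. A threshold of 1.5-fold gave 14 higher and 315 lower genes in V966M, 505 and 370 in 51B, 1431 between heterozygotes, 1547 between homozygotes, 56 called alike in both alleles and 20 in opposite directions. At 4-fold these were 2 and 1, 27 and 12, 30, 92, 0 and 0. Both follow from the threshold. A pseudocount of 0.1 FPKM gave 68 lower in V966M, 208 lower in 51B, 13 called alike and rho 0.310. With 5 FPKM there were 2 higher and 13 lower in V966M, 121 and 43 in 51B, 146 between heterozygotes, 303 between homozygotes, 1 alike and 1 opposite, with r 0.200 and rho 0.169. Without a filter r was 0.207 and rho 0.192, and with a mean of at least 5 FPKM there were 4 higher in V966M, r 0.302 and rho 0.324. Rescaling gave 13 higher and 8 lower in V966M, 212 between heterozygotes, 2 alike, 2 opposite and rho 0.316. Leaving out chromosome 3, which leaves 6089 genes, gave 4 and 19 in V966M, 85 and 56 in 51B, 204 between heterozygotes, 351 between homozygotes, 2 alike, 2 opposite and 7 lists apart from random lists in 51B, against 12. It also turned the cuticle list in V966M (median -0.29, percentile 39.2) and the neuronal (-0.0191, 29.7) and odorant-binding (-0.47, 0.03) lists in 51B. A mean of at least 5 FPKM turned the balancer marker list in 51B (0.68, 98.8). This filter left only y, e and twi, so that median was the value of twi alone, with y lower and e higher. Without genes sharing a locus, 3 were higher in V966M, 2 alike and 2 opposite, and r was 0.290. Calls without intervals, regardless of status, and without genes listed at 0 kept every count within 1.5 times. AGO2 kept its direction and its side of the threshold under both pseudocounts and rescaling. Of the calls of named genes, 75 held with a pseudocount of 0.1 FPKM, 51 held and 24 were lost with 5 FPKM, and 61 held and 14 were lost after rescaling, with no sign turned. The calling rule can miss small changes. At 2.5-fold, 86% and 68% of simulated changes were recovered in V966M and 51B, among genes with at least 5 FPKM in the heterozygote. Without the intervals 50 and 313 genes were called, against 45 and 306.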

Other observations

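Apart from the test of the cuticle (Cpr) and seminal fluid protein (Sfp) genes, whose bounds were set before their medians were computed, the tests given here were chosen after the result was seen, on the same data. Genes of fasting and insulin signalling, a list added after the data were seen, went both ways in 51B. Of 10 analysed members, daw, a ligand of the activin pathway, had 5.54 FPKM in the heterozygote and 23.9 FPKM in the homozygote, Thor, the translation inhibitor 4E-BP, had 142 and 362 FPKM, and Pepck, an enzyme of gluconeogenesis, had 407 and 958 FPKM. The call of sug (12.2 and 26.8 FPKM) was lost after rescaling, and CG6295 was lower (56.4 and 17.3 FPKM). In V966M none of the 10 was called. Of the peptidoglycan recognition genes, the neighbouring and near-identical PGRP-SC1a (10.5 and 2.44 FPKM in 51B) and PGRP-SC1b (9.78 and 2.14 FPKM) were lower, while PGRP-SA (log2 change 0.54) and PGRP-SD (0.06) were not called.

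The first pattern was the lower level of chromosome 4 and heterochromatin scaffold genes in both homozygotes, with 67 of 74 chromosome 4 genes below 0 in V966M and 74 of 74 in 51B after rescaling. Rescaling left a median of at most -0.385 in both alleles, which argues against scale. The lowest of 10000 lists matched to the chromosome 4 genes on expression and locus length was -0.165, which argues against locus length. The scaffold genes lay at -0.249 in V966M (lowest matched list -0.12) and -0.40 in 51B (-0.30). They are not on chromosome 4, so by definition its copy number alone cannot account for the whole pattern. In windows near the centromere, set per arm and of unlike size, medians were -0.18 in V966M and -0.32 in 51B on 2L (47 genes above 21.5 Mb), -0.35 and -0.44 on 2R (16 genes below 1 Mb), -0.10 and -0.22 on 3L (52 genes above 22.5 Mb), and -0.05 and -0.03, with intervals that include 0, on 3R (56 genes below 0.5 Mb). Copy number for the chromosome 4 genes themselves stays open, as does GC content, which was not tested. Under a change of copy number these genes were taken to spread no more than those of other arms in both alleles. The ratio of their SD to the median SD of other arms was 0.420 in 51B, as copy number would give, and 1.229 in V966M. A loss of Ago2 function that lowers genes in heterochromatin is a candidate explanation. The V966M heterozygote lay above the 51B heterozygote by 0.390 on chromosome 4, about as much as homozygote and heterozygote differed. On the scaffolds it lay above by 0.29 (interval 0.21 to 0.37). In the windows the heterozygotes differed by -0.04 on 2L (interval -0.24 to 0.09), 0.24 on 2R (0.14 to 0.40), -0.03 on 3L (-0.18 to 0.12) and 0.02 on 3R (-0.07 to 0.05). AGO2 itself was called higher in the V966M than in the 51B heterozygote (150.0 and 46.5 FPKM, log2 difference 1.39 after rescaling). A bound set after the data were seen took the heterozygotes to be nearly alike on chromosome 4 if loss of Ago2 function were the cause. The difference of 0.390 missed this bound. However, the bound assumes equal Ago2 function in both heterozygotes, which mRNA levels do not measure. The difference between heterozygotes therefore decides neither for nor against an effect of Ago2. Zygosity, AGO2 level and other differences between the 4 libraries cannot be told apart for the genes of chromosome 4 and the scaffolds.

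The second pattern was that accessory gland and digestive lists lay low, and cuticle and larval serum lists high, in both homozygotes. Homozygotes that were younger within the collection window may have such a profile, since seminal fluid genes gain and cuticle genes lose expression after eclosion. Among 25 Sfp genes the median log2 change was -0.52 in V966M and -0.64 in 51B, with 0 of 10000 random lists as low in either. Like the accessory gland list already seen to lie low, they encode seminal fluid proteins, so this outcome could be foreseen and adds little on age. The 40 other Cpr genes lay at percentile 99.82 in V966M and 86.68 in 51B, the latter short of the bound set, so age stays open. Cpr64Ac was known to be higher in 51B when the bound was set. Without chromosome 3 genes the accessory gland (9 genes left) and digestive (12 genes left) lists stayed at or below percentile 1.37 in both alleles. Genes on other chromosomes are by definition outside the reach of cis effects of chromosome 3. The low medians therefore did not rest on such effects alone. Effects of the balancer or of other third-chromosome differences on genes elsewhere were not tested. For the members on chromosome 3, cis effects stay open. The cuticle list kept 3 genes and a lowest percentile of 38.98 (39.2 in a separate draw of random lists), so for it such effects cannot be told apart.

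The third pattern was that 10 of 28 digestive enzyme genes were lower in the 51B homozygote. A smaller share of gut tissue as a whole was examined with 6 other gut epithelium genes, the analysed members of a list of 11 added after the data were seen. Their median was 0.48 and lower quartile 0.174 after rescaling, where the digestive list had a median of -0.45. These genes were thus not lower along with the digestive list. As deposited they stood above random lists (percentile 99.93), so they are no neutral measure of gut tissue and do not exclude a smaller share. A smaller share of the enzyme-producing part of the gut alone was not tested. The 12 members on other chromosomes, with Jon25Bi, Jon25Bii and Jon44E lower, had a median of -0.61 after rescaling and -0.48 as deposited. As deposited, 0 of 10000 random lists were as low. Differences on chromosome 3 cannot act in cis on these members, so the low list median did not rest on such effects alone. Whether the balancer or other third-chromosome differences act on genes elsewhere was not tested. Differences acting in cis stay open for the 7 lower of 16 members on chromosome 3 (43.8%). The list of fasting and insulin signalling genes had a median at percentile 91.37, between the bounds, so a nutritional state may contribute and cannot be told apart. Ago2 zygosity, the biological explanation that the design names, was not tested for this pattern and stays open.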
